A study of Mus musculus with 50 samples.

How the data were processed

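RNA-seq libraries of mouse embryonic stem (ES) cells and of epiblast-like cells (epiLC) were analysed, 32 of the 50 samples of the series. The other 18 samples, chromatin immunoprecipitation libraries and their inputs, were not analysed here. Per the labels' protocols, RNA was isolated with TRIzol and treated with DNase, and libraries were made with a TruSeq RNA kit. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

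The values came in 4 tables. The authors deposited FPKM values (fragments scaled to transcript length and library size) for the 12 libraries of V6.5 cells carrying short hairpins in 2i medium. Per the submitters' processing notes, these samples were processed with bcl2fastq 2.18, TopHat2 2.0.13, Cufflinks 2.2.1 and Bowtie2. The authors deposited TPM values (transcript shares scaled to the same total in each library) in the other 3 tables, which hold 6, 6 and 8 libraries. Per the submitters' processing notes, those samples were processed with bcl2fastq 2.18, STAR, RSEM and Bowtie2. The versions of STAR, RSEM and Bowtie2 were not given in the sources used here, and the notes name the mm10 build for both kinds of table.

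The FPKM table listed 17043 genes with 0 values at 0, so genes at 0 in any library are missing from it. It also held 1 further column of per-sample values, named for shHP1r replicate 2 and with values below 0, which was not used, while the FPKM column of that library was. Each TPM table listed 55421 genes. TPM keeps no depth, and the FPKM values left too few low values, without gene lengths, to recover what 1 read was worth. Sequencing depth is therefore unknown for every library, and no interval or floor that needs it is given. In an FPKM or TPM table a few abundant transcripts lower the values of all other genes, so scaling between libraries was tried as an alternative.

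From the deposited values, log2(value + 1) was computed, and genes with a value of at least 1 in at least 2 libraries of a table were tested. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. All libraries of a table entered 1 limma fit (limma 3.58.1 with statmod 1.5.0 in R 4.3.3) with a term per group, a variance trend and robust moderation. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Expression was tested only within a table, since the tables were normalized separately, and genes called in 2 tables were compared by Fisher's exact test. Control epiLC at 24 and 48 h and their knockdown counterparts lie in different tables, so their values are set side by side without a test. Where the 6 shGFP libraries served several comparisons, unchanged groups were simulated. All V6.5 hairpin libraries, the controls among them, were drawn independently around each gene's mean with the fitted spread.

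Gene lists were fixed before the data were examined. They cover catenin and Wnt pathway components, the Tcf and Lef family, Wnt target genes, naive, core, and formative and primed pluripotency, primitive streak and mesoderm, endoderm, neuroectoderm, trophoblast, germline and meiosis, 2-cell stage genes, Hox genes, the E2F6, HP1 and PRC1.6 complex, Polycomb PRC2, E2F cell cycle genes, p53 and apoptosis, stress and ATF4, the interferon response, fibroblast or feeder markers, glycolysis, cholesterol biosynthesis, imprinted genes, cell adhesion, mitochondrial transcripts and reference genes. List members were matched by symbol and counted by gene ID. Each list was tested against the other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With the estimated correlation, calls held only for the lists where the text says so. Sets of 200 genes with the largest rises and falls at 48 h of epiLC were also tested in the knockdowns.

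The genes named were set by a rule fixed in advance. It took Ctnnb1, E2f6, Cbx3, Tcf7, Lef1, Tcf7l1, Tcf7l2 and Hmga2. It took up to 10 largest rises and 10 largest falls among genes past the threshold whose libraries did not overlap between the groups and whose higher mean was at least 2, leaving out predicted genes, pseudogenes, ribosomal protein genes and small RNA genes. Where fewer than 5 passed in a direction, the smallest p filled up to 5 as values only. It took up to 4 members of each list with the smallest p, and Axin2, T, Cdx1, Cdx2, Sp5, Nanog, Esrrb, Klf4, Tfcp2l1, Pou5f1, Sox2, Fgf5, Otx2 and Dnmt3b. Some genes and the results that rest on them are not reported here.

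The alternatives fixed in advance were a minimum of 2-fold, a pseudocount of 0.1, no filter or a minimum of 5 in 2 libraries, no variance trend or robust moderation, a fit of the compared groups alone, each library left out in turn, the replicate number as a block, median-of-ratios scaling, controls split 3 and 3, an estimated correlation and sets of 100 genes. After the data were seen, a term for a set of 4 libraries with a high mitochondrial share, averaging of near-equal pairs of libraries, which leaves each knockdown as 1 sample, overlaps with the 96 h comparison, and epiLC sets without members of the fibroblast and interferon lists were added. The fits were tested on simulated data with 100 genes changed at each size. For shBcat in V6.5 cells, over 14407 genes, 70 of 100 genes changed by 1 on the log2 scale were recovered and 98 of those changed by 2. The corresponding numbers were 95 and 99 for QKO cells over 15562 genes, 98 and 99 for epiLC at 48 h over 16559 genes, and 99 and 99 for epiLC at 96 h over 15304 genes. Unchanged genes made up 4.55%, 7.62%, 6.64% and 6.60% of the calls in these comparisons. Changes were placed only in genes with a mean log2(value + 1) above 2. Libraries were drawn independently, without the near-equal pairs or the high mitochondrial set, so recovery in the real libraries may be lower. Coordinates came from a gene table on the GRCm38.p6 assembly, of which mm10 is another name. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.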

Results

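Gene expression was measured by RNA-seq in mouse ES cells of the V6.5 line, in a line labelled QKO, and in epiLC, the cells that ES cells form on the way to the post-implantation epiblast. The series asks which developmental genes are regulated by β-catenin and the proteins associated with it. V6.5 cells in 2i medium, in which inhibitors of MEK and GSK3 hold ES cells in the naive state, carried short hairpins against β-catenin (shBcat, n = 2), E2F6 (shE2F6, n = 2), HP1γ (labelled shHP1r, n = 2) or GFP as a control (shGFP, n = 6). QKO cells in 2i medium carried shBcat or shGFP (n = 3 each), with a time of 48 h whose starting point the sample titles do not give. The labels do not spell out QKO. Unmodified V6.5 cells in 2i and epiLC at 24 and 48 h had n = 2 each, as did epiLC with shBcat at 24, 48 and 96 h and control epiLC at 96 h. The labels of the control epiLC name no hairpin. Depth is unknown. Between 12446 and 14151 genes reached 1 FPKM per library in the V6.5 hairpin table, and between 13924 and 15351 reached 1 TPM in the others. Mitochondrial transcripts made up 20.4% and 19.3% of the values in shGFP replicates 3 and 4 and 22.9% and 22.3% in the shE2F6 libraries, against 6.23% to 10.3% in the other 8 V6.5 hairpin libraries. The shGFP libraries lay in pairs (1 and 2, 3 and 4, 5 and 6) whose median absolute log2 differences were 0.0506 to 0.0657, against 0.158 to 0.371 for the 12 pairings across them.

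The targeted genes were lower in the libraries labelled for them. Ctnnb1, which encodes β-catenin (ENSMUSG00000006932, GRCm38.p6 chromosome 9, 120933400 to 120960507), fell from 116 ± 20.3 FPKM (SD, n = 6) with shGFP to 6.59 ± 0.021 (n = 2) with shBcat, a log2 change of -3.93 (SE 0.17, adjusted p = 1.04e-06). E2f6, a repressor of the E2F family (ENSMUSG00000057469, chromosome 12, 16810909 to 16826752), fell from 10.0 ± 0.82 to 3.06 ± 0.69 FPKM with shE2F6, a log2 change of -1.45 (SE 0.15, adjusted p = 0.00102). Cbx3, which encodes HP1γ (ENSMUSG00000029836, chromosome 6, 51470154 to 51483704), fell from 63.5 ± 5.88 to 6.92 ± 0.46 FPKM with shHP1r, a log2 change of -3.02 (SE 0.12, adjusted p = 6.92e-07). The coordinates span whole genes, and the position of the hairpin sites within them is not known here. Ctnnb1 stood at 90.8 ± 2.33 FPKM with shE2F6 and 114 ± 9.9 with shHP1r, and did not pass the test in either (adjusted p = 0.183 and 0.986). In QKO cells Ctnnb1 fell from 505 ± 20.2 to 64.4 ± 17.1 TPM (n = 3 each), a log2 change of -2.98 (SE 0.18, adjusted p = 0.0108). That call was lost without shBcat replicate 2 (log2 change -2.98, adjusted p = 0.0569) or shGFP replicate 1 (-2.95, adjusted p = 0.0576). At 96 h of epiLC it fell from 445 ± 4.56 to 144 ± 2.15 TPM (n = 2 each), a log2 change of -1.62 (SE 0.04, adjusted p = 5.74e-06). With the V6.5 hairpin libraries averaged in pairs each knockdown is 1 sample, assumed to vary like the 3 shGFP pairs that alone give the spread. The fold changes then stayed as they were, while adjusted p rose to 0.184 for Ctnnb1, 0.744 for E2f6 and 0.107 for Cbx3.

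**Figure D1:**
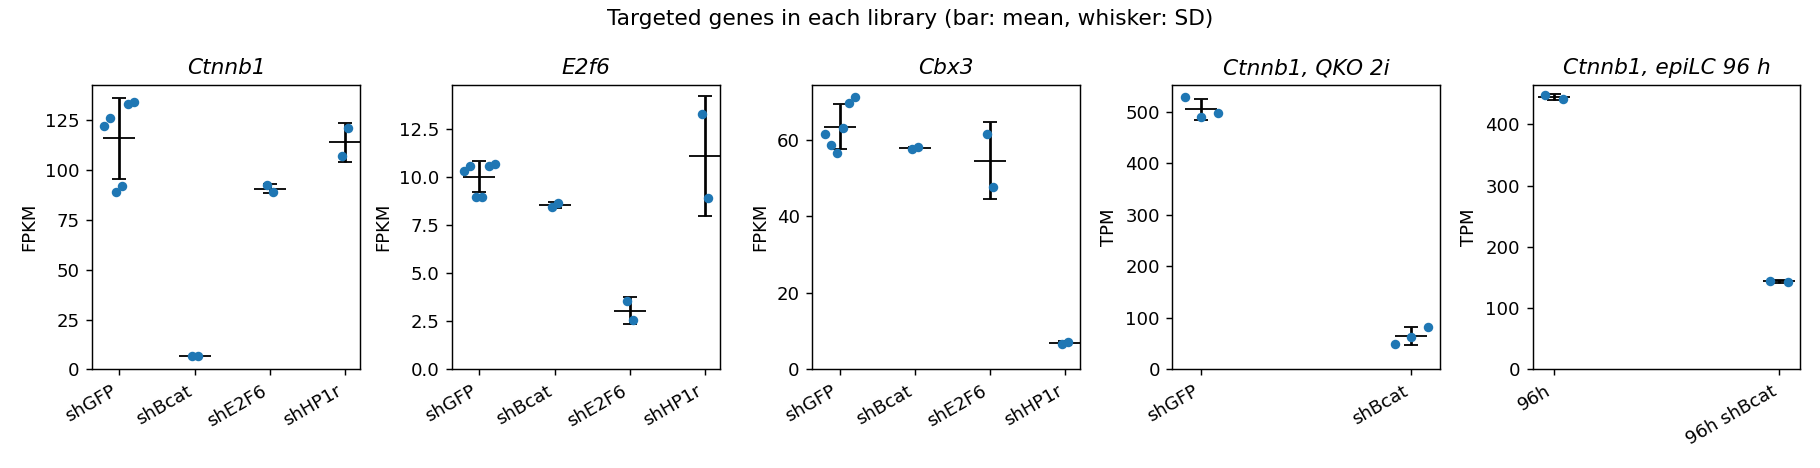
Expression of the targeted genes per library, in FPKM for Ctnnb1, E2f6 and Cbx3 in V6.5 2i cells and in TPM for Ctnnb1 in QKO 2i cells and epiLC at 96 h. Points are libraries, bars are group means and whiskers are SD; Ctnnb1 lay at 6.58 to 6.61 FPKM in the shBcat libraries and at 88.8 to 134 in the shGFP libraries.

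The shBcat comparison in V6.5 cells asks which genes depend on β-catenin in the naive state. With shBcat Axin2, a negative feedback gene of canonical Wnt signalling, dropped from 12.4 ± 0.33 FPKM (n = 6) to 0.928 ± 0.024 (n = 2), a log2 change of -2.80 (SE 0.11, adjusted p = 7.6e-07). The caudal homeobox gene Cdx1 went from 18.9 ± 8.6 to 0.107 FPKM (log2 change -4.03, SE 0.43, adjusted p = 0.0003), and Tnfrsf19 and Nkx1-2 changed by -1.93 and -3.15. Of 20 tested Wnt target genes 1 rose, 7 fell and 12 did not pass, or 2 and 9 when adjusted over the list alone (camera adjusted p = 5.09e-05; adjusted p = 0.061 with an estimated correlation). The riser was Sall1 (log2 change 0.79). Genes of the 2-cell stage fell together, 15 of 16 tested over all genes and 15 adjusted over the list alone, with a median log2 change of -1.61 (camera adjusted p = 9.45e-21; adjusted p = 0.061 with an estimated correlation). Among them Zscan4f, a telomere regulator of the 2-cell embryo, fell from 31.6 ± 1.7 to 2.53 ± 0.55 FPKM, although reads of the Zscan4 copies may be split between them and single members are uncertain. Of 6 tested Hox genes 3 fell and 3 did not pass, or 5 fell adjusted over the list alone (camera adjusted p = 5.09e-05; adjusted p = 0.0783 with an estimated correlation). The imprinted zinc finger gene Plagl1 and the meiotic genes Stra8 and Dazl changed by -2.78, -2.33 and -1.52 on the log2 scale (adjusted p = 1.58e-05, 0.00202 and 0.00217). Without shBcat replicate 1 or 2 the Wnt targets that fell were 3 in either case, with Sp5 (adjusted p = 0.0905 and 0.0915), Notum (0.0907 and 0.0648), T (0.106 and 0.0719) and Tcf7 (0.352 and 0.278) no longer called. Tcf7 was also lost without shGFP replicates 1, 2, 4 and 5 (0.0719, 0.0616, 0.0578 and 0.0642). The 2-cell genes that fell were then 8 and 7, and the Hox genes 2 and 1.

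Otx2, a homeobox gene of the anterior epiblast, rose with shBcat from 1.31 ± 0.32 to 6.61 ± 0.21 FPKM (log2 change 1.73, SE 0.16, adjusted p = 0.000111). Lmx1b, Hesx1 and Sox1 rose by 2.19, 2.14 and 1.29 (adjusted p = 1.09e-06, 0.000111 and 0.00052). Of 11 tested neuroectoderm genes 3 rose and 8 did not pass, or 5 rose adjusted over the list alone (camera adjusted p = 0.000523; adjusted p = 0.374 with an estimated correlation). Of 20 tested stress and ATF4 genes 6 rose and 14 did not pass, or 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00317; adjusted p = 0.827 with an estimated correlation), with Chac1 at 7.33 ± 0.49 against 2.45 ± 0.49 FPKM and Ddit3 at 8.78 against 3.45. Of 26 naive pluripotency genes 7 fell and 19 did not pass, or 1 rose and 8 fell adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0557). It passed without shBcat replicate 2 (0.0377) or shGFP replicate 4 (0.0493), 5 (0.0386) or 6 (0.0460). Of 24 formative and primed genes 5 rose, 3 fell and 16 did not pass, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.571), and of 14 reference genes 14 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 0.571). Over 14407 genes, 505 rose and 750 fell, 1255 in all. That count was 212 without shBcat replicate 1 and 224 without shBcat replicate 2. Either way 1 neuroectoderm gene and 2 stress genes rose, 2 formative genes rose and 1 fell, and limma called 0 naive genes, with 1 higher and 8 or 7 lower at an unadjusted p under 0.05. The naive genes that fell were 4 without shGFP replicate 1, 2, 5 or 6. With libraries averaged in pairs limma called 0 genes, with 702 at an unadjusted p under 0.05.

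E2F6 takes part in silencing germline genes in ES cells. With shE2F6 the meiotic cohesin gene Smc1b went from 1.38 ± 0.16 FPKM (n = 6) to 54.9 ± 10 (n = 2), a log2 change of 4.55 (SE 0.17, adjusted p = 2.78e-07). Hormad1, a protein of the meiotic chromosome axis, went from 14.3 ± 1.3 to 106 ± 4.2 FPKM, and Zcwpw1 from 2.04 ± 0.19 to 19.1 ± 0.49. The log2 changes of Stag3 and Rnf212 were 1.94 and 2.01 (adjusted p = 2.76e-05 and 6.38e-07). Of 33 tested germline and meiosis genes 12 rose, none fell and 21 did not pass, and 20 rose adjusted over the list alone (median log2 change 0.68, camera adjusted p = 6.96e-27; adjusted p = 0.0527 with an estimated correlation). Both shE2F6 libraries and shGFP replicates 3 and 4 carried the high mitochondrial share given above. With a term for that set of 4 libraries, chosen after the data were seen, 15 germline members rose (camera adjusted p = 3.69e-31; adjusted p = 0.014 with an estimated correlation). The 13 mitochondrial transcripts had a median log2 change of 1.18, with 13 not passing over all genes or adjusted over the list alone (camera adjusted p = 2.95e-09; adjusted p = 0.913 with an estimated correlation). In the 2-cell list, of 16 genes 16 did not pass, and 12 fell adjusted over the list alone (camera adjusted p = 0.00827). In the stress and ATF4 list, of 20 genes 20 did not pass, and 10 fell adjusted over the list alone (camera adjusted p = 0.0223). Of 22 glycolysis genes 22 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 0.0339). For these 3 lists adjusted p was 0.913 with an estimated correlation. Without shE2F6 replicate 1 their camera adjusted p was 0.300, 0.114 and 0.300, and for glycolysis it was 0.0576, 0.0636, 0.215 and 0.188 without shGFP replicates 1, 2, 3 and 4, and 0.143 with median-of-ratios scaling. Without shGFP replicates 3 and 4 limma called 12 and 9 mitochondrial transcripts higher, and 7 and 7 of the 2-cell, 10 and 10 of the stress and 2 and 1 of the glycolysis genes lower.

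Over all genes 59 rose and 94 fell with shE2F6, 153 in all. The median log2 change of all genes was -0.20, median-of-ratios scaling shifted it by 0.18, and 152 genes then rose and 88 fell. The count was 30 and 19 without shE2F6 replicates 1 and 2, and 43, 41, 4165, 3435, 38 and 35 without shGFP replicates 1, 2, 3, 4, 5 and 6. With libraries averaged in pairs limma called 0 genes, with 209 at an unadjusted p under 0.05.

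HP1γ binds methylated histone H3 in heterochromatin. With shHP1r the genes of the 2-cell stage rose, 16 of 16 tested, with a median log2 change of 2.05 and 16 adjusted over the list alone (camera adjusted p = 6.6e-23; adjusted p = 0.0673 with an estimated correlation). Zscan4f went from 31.6 ± 1.7 FPKM (n = 6) to 160 ± 14 (n = 2). Rpia, of the pentose phosphate pathway, went from 16.5 ± 0.99 to 93.7 ± 22 FPKM (log2 change 2.42, SE 0.12, adjusted p = 2.68e-06), and Tnfrsf22 from 56.5 ± 14 to 333 ± 74. Of 33 germline genes 10 rose and 23 did not pass, or 17 rose adjusted over the list alone (camera adjusted p = 5.36e-06; adjusted p = 0.394 with an estimated correlation), among them the synaptonemal complex gene Syce1 (log2 change 1.12). Of 20 imprinted genes 4 rose and 16 did not pass, or 9 rose adjusted over the list alone (camera adjusted p = 0.000359; adjusted p = 0.395 with an estimated correlation), with H19 at 11.2 against 2.86 FPKM. Of 11 endoderm genes 4 rose and 7 did not pass, or 5 adjusted over the list alone (camera adjusted p = 0.00648; adjusted p = 0.617 with an estimated correlation), with Dab2 at 1.69 against 0.493 FPKM. Of 11 trophoblast genes 5 rose and 6 did not pass, or 6 adjusted over the list alone (camera adjusted p = 0.0243, and 0.0731 without shHP1r replicate 1; adjusted p = 0.394 with an estimated correlation). Of 9 fibroblast or feeder markers 5 rose and 4 did not pass, or 6 adjusted over the list alone (camera adjusted p = 0.0029; adjusted p = 0.394 with an estimated correlation). Of 9 interferon genes 3 rose and 6 did not pass, or 4 adjusted over the list alone (camera adjusted p = 0.00374; adjusted p = 0.400 with an estimated correlation), among them Oasl2 at 1.72 against 0.488 FPKM. Without shHP1r replicate 1 the genes that rose were 13 of the 2-cell, 3 of the germline, 1 of the imprinted, 1 of the endoderm and 2 of the interferon list, and limma called 0 trophoblast and 0 fibroblast genes, with 5 and 3 higher at an unadjusted p under 0.05. Without shHP1r replicate 2 imprinted genes that rose were 10. Germline genes that rose were 6 without shGFP replicate 5 or 6, trophoblast genes 3 without replicate 3, 4, 5 or 6, and fibroblast markers 3 without replicate 4, 5 or 6.

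In the main fit fewer genes fell than rose with shHP1r, while with the library set term more fell than rose. Tnpo1, a nuclear import receptor, went from 49.7 to 26.6 FPKM (log2 change -0.89, SE 0.10, adjusted p = 0.000209), and the amino acid transporter Slc7a1 changed by -0.97 (adjusted p = 0.00179). Of 28 E2F cell cycle genes 2 fell and 26 did not pass, or 7 fell adjusted over the list alone (camera adjusted p = 1.18e-06; adjusted p = 0.394 with an estimated correlation). Of 24 members of the E2F6, HP1 and PRC1.6 complex list 1 rose, 3 fell and 20 did not pass, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.0029; adjusted p = 0.0673 with an estimated correlation). That list holds Cbx3, the target itself, and 1 member fell without shHP1r replicate 1. Of the E2F genes 6 fell without shHP1r replicate 2 and 1 without shGFP replicate 2. With shHP1r replicate 1 or any other shGFP library left out limma called 0 of them, with 0 to 13 lower at an unadjusted p under 0.05. Over all genes 848 rose and 245 fell, 1093 in all, and the count was 420 without shHP1r replicate 1. The library set term gave 1460 rising and 1836 falling genes. With libraries averaged in pairs limma called 0 genes, with 754 at an unadjusted p under 0.05.

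**Figure D2:**
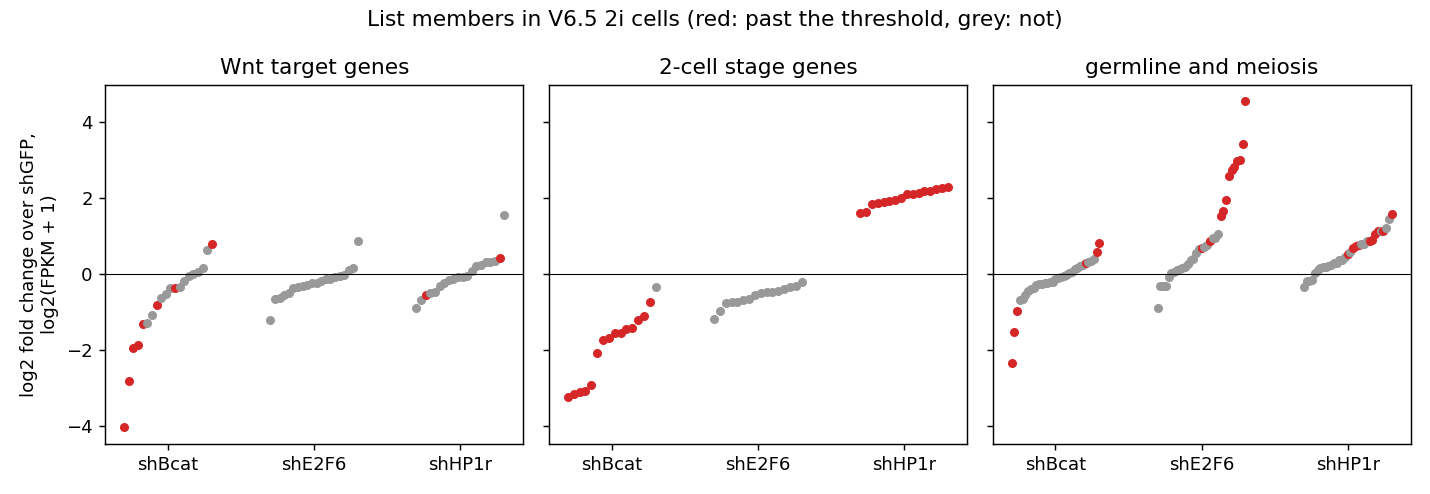
Log2 fold change over shGFP, on the log2(FPKM + 1) scale, of each tested member of the Wnt target, 2-cell stage and germline lists with shBcat, shE2F6 and shHP1r in V6.5 2i cells. Red points passed the adjusted p threshold and grey points did not; 15 of 16 members of the 2-cell list fell with shBcat and 16 of 16 rose with shHP1r.

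The knockdowns were also compared with one another. Genes of the 2-cell stage were higher with shHP1r than with shBcat, 16 of 16 over all genes, with a median log2 difference of 3.66 (camera adjusted p = 2.46e-30). The same 16 were higher adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.0401). They were higher with shHP1r than with shE2F6 too, 16 of 16, with a median difference of 2.65 and 16 adjusted over the list alone (camera adjusted p = 1.36e-14; adjusted p = 0.307 with an estimated correlation), and 7 of 16 were higher with shE2F6 than with shBcat, or 9 adjusted over the list alone with a median difference of 0.88 (camera adjusted p = 2.36e-12; adjusted p = 0.125 with an estimated correlation). Of 20 Wnt target genes 5 were higher and 2 lower with shHP1r than with shBcat, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000826; adjusted p = 0.0935 with an estimated correlation). Of 33 germline genes 19 were higher and none lower with shE2F6 than with shBcat, or 20 and 1 adjusted over the list alone (camera adjusted p = 1.92e-17; adjusted p = 0.125 with an estimated correlation). Of 20 stress and ATF4 genes 10 were lower with shE2F6 than with shBcat, or 14 adjusted over the list alone (camera adjusted p = 0.000218; adjusted p = 0.535 with an estimated correlation). That number was 3 without any 1 of the 4 libraries, the germline number was 12 without shBcat replicate 2 or shE2F6 replicate 2, and the Wnt numbers were 3 and 1 without either shBcat replicate. In all 2196 genes differed between shE2F6 and shBcat (722 higher, 1474 lower), 1341 between shHP1r and shBcat (1004 and 337) and 2230 between shHP1r and shE2F6 (1774 and 456). Median-of-ratios scaling shifted the medians of the comparisons with shE2F6 by 0.21 and -0.22 and gave 1325 higher and 1350 lower against shBcat, and 1514 higher with shHP1r and 967 lower. Both shE2F6 libraries carried the high mitochondrial share, and with the term for that set of libraries 714 of the 2196 genes and 620 of the 2230 kept their call. The first count was 198 and 172 without shBcat replicates 1 and 2, and 476 and 183 without shE2F6 replicates 1 and 2. The second was 604, 583 and 877 without shBcat replicates 1 and 2 and shHP1r replicate 1, and the third 667, 511 and 578 without shE2F6 replicates 1 and 2 and shHP1r replicate 1. With libraries averaged in pairs, 1 sample was set against 1 with the spread of the shGFP pairs alone, and limma called 144 genes between shHP1r and shBcat, and 0 in the comparisons of shE2F6 with shBcat and with shHP1r, with 731 and 942 at an unadjusted p under 0.05.

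Overlaps of the knockdowns share their control libraries. With shBcat and shE2F6, 8 genes rose in both and 18 fell in both, where lists of these sizes drawn independently share 2.07 and 4.89, and 9 genes moved in opposite directions. With shBcat and shHP1r 60 rose and 35 fell in both (29.7 and 12.8 for independent lists) and 230 moved in opposite directions. Under the library set term, this pair had 175 rising and 451 falling in both (116 and 297 for independent lists). There 496 moved in opposite directions, so shared changes then outnumbered opposite ones. With shE2F6 and shHP1r 11 rose and 5 fell in both (3.47 and 1.6) and 7 moved in opposite directions. Simulated unchanged groups gave a mean overlap of 0 over 50 draws. Independent lists of their calls would share 0 too, so this overlap cannot show an effect of shared controls. The simulation also held neither the pairs of shGFP libraries nor the set with a high mitochondrial share. The median of 20 splits of the controls into 3 and 3 was 4, 38 and 2.5 shared genes. Across genes, which are not independent replicates, the fold changes of these pairs had r = -0.14, -0.02 and -0.20 where the simulated groups had 0.249, 0.249 and 0.248. Their covariances were -0.0244, -0.00301 and -0.0342, against 0.0116, 0.0117 and 0.0116 for the simulated groups, differences of -0.0360, -0.0147 and -0.0458. With the library set term r was 0.13, -0.07 and 0.01, and the covariances were 0.0128, -0.0115 and 0.000764. Unchanged groups were not simulated with that term, so these covariances have no simulated value to be set against. Over the 20 splits of the controls r ranged from -0.51 to 0.19, from -0.22 to -0.02 and from -0.53 to 0.11.

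In QKO cells 15 of 21 interferon genes and 5 of 20 fibroblast or feeder markers were lower with shBcat. Ifi27 went from 69.4 ± 8.29 TPM to 15.5 ± 1.66 (n = 3 each), a log2 change of -2.09 (SE 0.11, adjusted p = 0.0025), and passed with each library left out in turn. Isg15, a ubiquitin-like protein induced by interferon, went from 16.0 ± 8.54 to 1.07 ± 0.075 TPM (adjusted p = 0.0408). Of the interferon genes 6 did not pass, and 21 fell adjusted over the list alone (camera adjusted p = 7.21e-15; adjusted p = 0.517 with an estimated correlation). Of the fibroblast or feeder markers 15 did not pass, and 19 fell adjusted over the list alone (camera adjusted p = 3.03e-11; adjusted p = 0.517 with an estimated correlation), with the collagen gene Col3a1 at 170 ± 82.6 against 29.2 ± 6.58 TPM. Summed over the fibroblast list, the shBcat libraries held 1505, 1461 and 1409 TPM and the shGFP libraries 2006, 2831 and 1764. Most of each shBcat sum was Fn1, at a mean of 1103 TPM with shBcat and 1070 with shGFP (adjusted p = 0.648), while Col1a1, Dcn and Postn went from 91.7, 33.5 and 10.9 TPM to 18.2, 6.45 and 1.57. Of 23 glycolysis genes 1 rose and 22 did not pass, or 20 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.08e-14; adjusted p = 0.517 with an estimated correlation), and of 22 cholesterol genes 1 rose and 21 did not pass, or 15 rose adjusted over the list alone (camera adjusted p = 4.87e-11; adjusted p = 0.517 with an estimated correlation). Of 16 Wnt target genes 1 fell and 15 did not pass, or 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.936). In all 91 genes rose and 243 fell of 15562, 334 in total, and median-of-ratios scaling gave 152 and 171. The count was 8 without shGFP replicate 1, 9 without shBcat replicate 3, 11 without shBcat replicate 2, 181 without shGFP replicate 2 and 932 without shGFP replicate 3. The interferon genes that fell were 10, 2 and 1 without shBcat replicates 1, 2 and 3, and 1, 13 and 17 without shGFP replicates 1, 2 and 3. The fibroblast markers that fell were 2 without shBcat replicate 1, and 10 and 18 without shGFP replicates 2 and 3. Without shBcat replicate 2 or 3 or shGFP replicate 1 limma called 0 of them, with 19 lower at an unadjusted p under 0.05. Glycolysis genes that rose were 9 and 7 without shBcat replicate 1 and shGFP replicate 3. Otherwise limma called 0, with 18 higher at an unadjusted p under 0.05. Cholesterol genes that rose were 3 without shGFP replicate 3. Without shBcat replicate 2 or 3 or shGFP replicate 1 or 2 limma called 0, with 12 to 17 higher at an unadjusted p under 0.05. Of the Wnt targets 2 fell without shGFP replicate 3, and with any other library left out limma called 0, with 2 to 4 lower at an unadjusted p under 0.05. Isg15 and Col3a1 each lost their call without shBcat replicate 1 (adjusted p = 0.0513 and 0.062), 2 (0.157 and 0.163) or 3 (0.124 for both) or shGFP replicate 1 (0.138 for both).

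**Figure D3:**
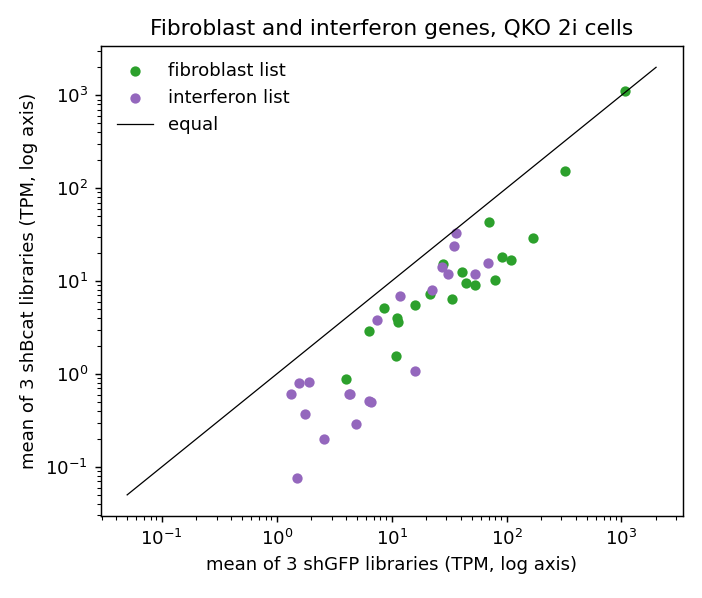
Mean TPM of the 3 shGFP libraries (x axis, log scale) against the mean of the 3 shBcat libraries (y axis, log scale) in QKO cells for members of the fibroblast (green) and interferon (purple) lists, with the line of equal values. Of the tested members 5 of 20 fibroblast and 15 of 21 interferon genes fell past the threshold.

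The effect of shBcat was set beside itself in V6.5 and QKO cells, whose tables were normalized separately. Among 12511 genes tested in both, 12 fell in both, Ctnnb1 among them, where independent lists share 8.80 (Fisher's exact test, two-sided, p = 0.291), and 11 moved in opposite directions. The fold changes had r = -0.02 across genes, which are not independent replicates. Axin2, at a log2 change of -2.80 in V6.5 cells, was not called in QKO cells, and the difference between the lines was not tested. Already with shGFP, Axin2, Cdx1, Sp5 and T stood at 5.82, 1.51, 0.04 and 0.167 TPM in QKO cells. In unmodified V6.5 cells in 2i, from another table, they stood at 22.5, 53.3, 1.335 and 1.655 TPM. The missing call therefore does not show that the knockdown spares active Wnt targets in QKO cells.

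The formation of epiLC was followed in unmodified V6.5 cells. At 24 h genes of the formative epiblast rose and naive pluripotency genes fell. Dnmt3b, a de novo DNA methyltransferase, went from 13.4 to 355 TPM (n = 2 each), a log2 change of 4.63 (SE 0.06, adjusted p = 3.48e-08), and the POU gene Pou3f1 from 0.365 to 45.9. Nanog went from 603 to 46.9 TPM (log2 change -3.66, SE 0.05, adjusted p = 3.45e-08), and Tfcp2l1 from 81.9 to 2.04. Of 27 formative and primed genes 24 rose, 2 fell and 1 did not pass, and the same numbers rose and fell adjusted over the list alone (camera adjusted p = 9.08e-08; adjusted p = 0.155 with an estimated correlation). Of 26 naive genes 3 rose, 22 fell and 1 did not pass, or 3 and 23 adjusted over the list alone (camera adjusted p = 4.76e-06; adjusted p = 0.155 with an estimated correlation). Of 10 core pluripotency genes 8 rose, 1 fell and 1 did not pass, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.005; adjusted p = 0.403 with an estimated correlation). In all 5992 genes rose and 6586 fell of 16559.

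At 48 h Fgf5, the growth factor that marks the primed epiblast, stood at 26.4 ± 2.4 TPM against 0.02 in 2i (log2 change 4.75, SE 0.08, adjusted p = 3e-08), and Dusp6, a target of ERK signalling, at 282 ± 29 against 0.365. Klf2 went from 172 to 5.13 TPM. Hmga2, a chromatin protein of early epiblast cells, went from 4.68 ± 0.06 to 90.8 ± 0.73 TPM (log2 change 4.01, SE 0.05, adjusted p = 1.98e-08), and Ctnnb1 from 367 ± 1.28 to 604 ± 0.35. Of 26 naive genes 1 rose, 24 fell and 1 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 3.13e-12; adjusted p = 0.0954 with an estimated correlation), and of 27 formative genes 26 rose and 1 fell, over all genes or adjusted over the list alone (camera adjusted p = 1.29e-07; adjusted p = 0.117 with an estimated correlation). All 4 Tcf and Lef family genes rose, over all genes or adjusted over the list alone, 3 with median-of-ratios scaling, while the list missed the threshold (camera adjusted p = 0.131). Of 14 PRC2 genes 4 rose, 8 fell and 2 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 0.0527). That p was 0.0339 with median-of-ratios scaling, which gave 2 and 9, and 0.0405, 0.0445 and 0.0462 without epiLC 48 h replicate 2 and 2i replicates 1 and 2. Without 2i replicate 1 or epiLC 48 h replicate 1, 2 PRC2 genes rose. In all 7474 genes rose and 5093 fell, and median-of-ratios scaling gave 6449 and 6039.

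From 24 to 48 h Hox and endoderm genes rose. The actin-binding protein gene Tagln went from 3.4 to 242 TPM (log2 change 5.80), and H19 from 3.21 to 79.1. Of 23 Hox genes 21 rose, 1 fell and 1 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 0.000166; adjusted p = 0.287 with an estimated correlation). Of 14 endoderm genes 14 rose, over all genes or adjusted over the list alone (camera adjusted p = 0.000367; adjusted p = 0.198 with an estimated correlation). Markers of fibroblasts, among them Tagln, rose with these lists, 13 of 15 with 2 lower, over all genes or adjusted over the list alone (camera adjusted p = 0.00273; adjusted p = 0.198 with an estimated correlation). Of 15 interferon genes 11 rose, 2 fell and 2 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 0.0412, and 0.0501 without epiLC 24 h replicate 1; adjusted p = 0.228 with an estimated correlation). Nanog went up from 46.9 to 166 TPM (log2 change 1.80, SE 0.05, adjusted p = 4.79e-07) while Dnmt3b went down from 355 to 141. Of 28 E2F cell cycle genes 2 rose, 23 fell and 3 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 3.72e-06; adjusted p = 0.216 with an estimated correlation). In all 7490 genes rose and 4789 fell, and median-of-ratios scaling, which shifted the median of all genes by -0.11, gave 6254 and 5976.

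The 200 genes that rose most and the 200 that fell most at 48 h of epiLC were followed in the 2i knockdowns. These sets were not tested with single libraries left out, so their counts may rest on 1 library. With shBcat in V6.5 cells, 33 of 122 tested genes of the rising set rose and 3 fell (camera adjusted p = 2.01e-13), and of 180 genes of the falling set 5 rose and 48 fell (4.54e-11). With shHP1r 23 of the rising set rose and none fell (3.55e-12), and 5 of the falling set rose and 7 fell (0.00815). With shE2F6 2 genes of the rising set fell (0.581), and 3 of the falling set rose and 2 fell (0.990). Under the library set term, the rising set fell past the threshold with shE2F6 (0.000605) and the falling set rose (0.00716). In QKO cells with shBcat 11 of 147 genes of the rising set fell and none rose (4.42e-08), and 12 of 191 of the falling set rose and 5 fell (1.74e-09). Fibroblast markers fell in the same QKO comparison, and at 48 h of epiLC 13 of 15 tested members of their list rose, 1 fell and 1 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 0.00121; adjusted p = 0.141 with an estimated correlation). Of the 147 genes 93, or 63.3%, ranked the 3 shGFP libraries of QKO cells in the order of the fibroblast median, as did 25.6% of 15521 tested genes outside the fibroblast and interferon lists. Without the 6 members of those lists, a setting chosen after the data were seen, 9 of 141 genes fell and none rose (camera adjusted p = 4.64e-07). With an estimated correlation adjusted p was 0.294 for both sets with shBcat in V6.5 cells, for the rising set with shHP1r and for the falling set in QKO cells, 0.709 for the falling set with shHP1r and 0.462 for the rising set in QKO cells.

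Control epiLC and epiLC with shBcat at 24 and 48 h came from tables normalized separately, so their mean TPM values are given side by side (n = 2 each) without a test. Table and knockdown coincide here, so no gap below can be assigned to the knockdown. Gapdh and Actb, reference genes named here outside the rule, differed too. At 48 h Gapdh stood at 2630 in controls and 4245 with shBcat, and Actb at 2563 and 1412. Ctnnb1 stood at 399 ± 1.94 in controls and 94.7 ± 0.32 with shBcat at 24 h, and at 604 ± 0.35 and 105 ± 2.67 at 48 h. Hmga2 stood at 5.84 ± 0.40 and 7.80 ± 0.19 at 24 h and at 90.8 ± 0.73 and 12.7 ± 0.31 at 48 h. Nanog stood at 46.9 and 55.3 at 24 h and at 166 ± 13.1 and 67.4 ± 4.51 at 48 h. The streak gene T stood at 0.275 ± 0.092 and 0.595 ± 0.163 at 24 h and at 3.86 ± 0.55 and 1.30 ± 0.34 at 48 h. Dnmt3b stood at 355 ± 1.82 and 123 ± 0.57 at 24 h and at 141 and 119 at 48 h. Otx2 stood at 31.4 ± 1.22 and 17.6 ± 0.021 at 24 h and at 22 ± 0.37 and 6.17 ± 0.078 at 48 h. Other genes had higher values with shBcat at 48 h. Pou5f1 stood at 1257 ± 32.3 and 873 ± 13.6 at 24 h and at 343 ± 8.95 and 604 ± 2.34 at 48 h. Sox2 stood at 92.6 and 86.5 at 24 h and at 48.4 ± 1.07 and 67.6 ± 0.74 at 48 h. Lef1 stood at 47.5 and 29.6 at 24 h and at 16.0 ± 0.23 and 28.3 ± 0.26 at 48 h, and Cdx1 at 0.535 and 1.51 at 24 h and at 0.585 and 1.6 at 48 h. Summed over the fibroblast or feeder list, the 48 h libraries held 859 and 908 TPM in controls and 377 and 414 with shBcat. The interferon list summed to 377 and 401 TPM in controls and 178 and 185 with shBcat at 48 h. At 24 h the fibroblast sums were 296 and 299 in controls and 332 and 346 with shBcat. At 96 h, within 1 table, Hmga2 stood at 81.3 ± 5.11 and 61.9 ± 2.75 (log2 change -0.39, SE 0.07, adjusted p = 0.0179), a call lost without control replicate 1 (0.0929) or shBcat replicate 1 (0.0815). Nanog stood at 157 ± 2.52 and 146 ± 15.5 at 96 h (adjusted p = 0.501), and Otx2 at 9.11 ± 1.28 and 8.81 ± 0.63 (log2 change -0.04, SE 0.10, adjusted p = 0.876).

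At 96 h of epiLC shBcat and control libraries share a table, but the control labels name no hairpin. Effects of carrying a hairpin are therefore not separated from the loss of β-catenin in this comparison. Glycolytic genes were lower with shBcat. Ldha, lactate dehydrogenase, went from 1211 ± 5.6 TPM to 547 ± 4.9 (n = 2 each), a log2 change of -1.14 (SE 0.04, adjusted p = 1.63e-05), and Pgk1 from 951 to 454. Bnip3, Egln3 and Ndrg1, which hypoxia induces, changed by -1.65, -1.94 and -2.05. Of 23 glycolysis genes 18 fell and 5 did not pass, or 1 rose and 20 fell adjusted over the list alone (camera adjusted p = 1.64e-23). Of 22 cholesterol genes 11 fell and 11 did not pass, or 20 fell adjusted over the list alone (camera adjusted p = 5.71e-14; adjusted p = 0.0967 with an estimated correlation). Atf5, of the stress and ATF4 list, rose with shBcat to 109 ± 8.8 from 42.8 ± 6.8 TPM (log2 change 1.33, SE 0.10, adjusted p = 0.000551) and Nupr1, Trib3 and Ddit3 were higher by 1.19, 1.12 and 1.04. Of 24 stress and ATF4 genes 11 rose, 3 fell and 10 did not pass, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.00016; adjusted p = 0.226 with an estimated correlation). Of 18 p53 genes 8 rose and 10 did not pass, or 10 rose adjusted over the list alone (camera adjusted p = 2.66e-08), with Mdm2, the ubiquitin ligase of p53, at 122 against 90.5 TPM. Of 13 mitochondrial transcripts 6 rose and 7 did not pass, over all genes or adjusted over the list alone (2.4e-06), and the mitochondrial share was 3.91% and 3.83% in the control libraries and 4.87% and 4.76% with shBcat.

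At 96 h Cdh1, E-cadherin, went with shBcat from 171 ± 3.7 to 121 ± 5.4 TPM (log2 change -0.50, SE 0.05, adjusted p = 0.00153), the tight junction gene Cldn6 changed by -0.83, and Fgf8, a growth factor of the epiblast, by -1.15. Of 23 adhesion genes 2 rose, 10 fell and 11 did not pass, or 3 and 13 adjusted over the list alone (camera adjusted p = 1.06e-05). Of 13 interferon genes 6 fell and 7 did not pass, or 9 fell adjusted over the list alone (camera adjusted p = 1.06e-05). The calls of the glycolysis, p53, mitochondrial, adhesion and interferon lists held with an estimated correlation (adjusted p = 0.0458 for each). Of 23 Wnt target genes 4 fell and 19 did not pass, or 2 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.0555, but 0.0206 without control replicate 1, 0.00873 without shBcat replicate 2 and 0.0349 with median-of-ratios scaling). Its falls were 2 and 1 without control replicates 1 and 2, and 2 and 3 without shBcat replicates 1 and 2. T was lost without each of these 4 in turn (adjusted p = 0.137, 0.0665, 0.104 and 0.0998), as was Cdx2 (0.0698, 0.211, 0.165 and 0.0861), and Lef1 without control replicate 2 (0.0559). Of 26 catenin and Wnt pathway components 1 fell and 25 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 0.00307; adjusted p = 0.464 with an estimated correlation), and that call was lost without control replicate 2 (0.0519) or shBcat replicate 1 (0.0945). The 1 that fell was Ctnnb1, the target itself, whose fall was set by the design and also entered the test of that list. Of 18 streak and mesoderm genes 3 fell and 15 did not pass, or 3 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.0356; adjusted p = 0.502 with an estimated correlation), and the call was lost without control replicate 2 (0.302) or shBcat replicate 1 (0.0945). Of 14 reference genes 3 fell and 11 did not pass, or 5 fell adjusted over the list alone (camera adjusted p = 3.5e-05; adjusted p = 0.0967 with an estimated correlation). Among the 3 were Gapdh and Pgk1 (log2 change -0.26 and -1.06), which are also members of the glycolysis list. Without control replicates 1 and 2 and shBcat replicates 1 and 2 the falls were 3, 2, 5 and 6 of the cholesterol genes, 6, 5, 6 and 5 of the adhesion genes, 4, 2, 3 and 3 of the interferon genes and 2, 1, 2 and 2 of the streak genes. The rises were then 3, 3, 5 and 2 of the p53 genes and 6, 8, 9 and 7 of the stress genes. In all 350 genes rose and 388 fell of 15304, 738 in total, while median-of-ratios scaling gave 419 and 348, and the count was 372 and 274 without control replicates 1 and 2, and 394 and 454 without shBcat replicates 1 and 2.

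**Figure D4:**
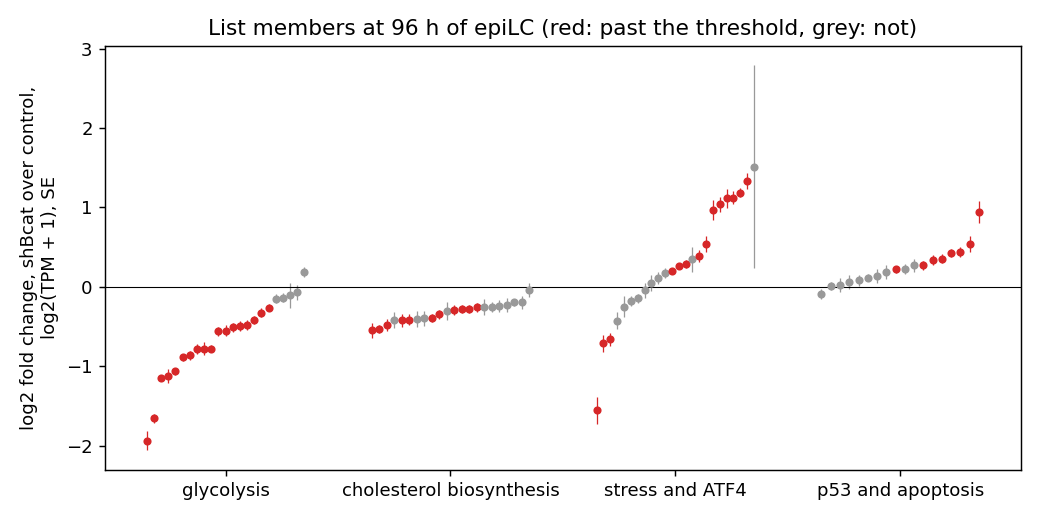
Log2 fold change with its SE, on the log2(TPM + 1) scale, of tested members of the glycolysis, cholesterol, stress and ATF4, and p53 lists with shBcat against control epiLC at 96 h. Red points passed the adjusted p threshold and grey points did not; 18 of 23 glycolysis genes fell and 8 of 18 p53 genes rose.

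With shBcat, the passage from 24 to 48 h raised Fgf5 from 8.87 to 19.5 TPM (n = 2 each) and lowered Esrrb from 25.8 to 9.12 (log2 change -1.40, SE 0.08, adjusted p = 3.86e-05). Of 18 genes of the 2-cell list 18 rose, over all genes or adjusted over the list alone (camera adjusted p = 1.02e-15; adjusted p = 0.204 with an estimated correlation). Of 24 naive genes 3 rose, 17 fell and 4 did not pass, or 4 and 17 adjusted over the list alone (camera adjusted p = 5.4e-06; adjusted p = 0.204 with an estimated correlation). Of 13 fibroblast markers 5 rose, 1 fell and 7 did not pass, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0394, but 0.0630 without the 24 h replicate 1 and 0.0686 without the 48 h replicate 2; adjusted p = 0.285 with an estimated correlation), and 2 rose without any 1 of the 4 libraries. Hoxb2 rose from 5.22 to 24.6 TPM, with 15 of 25 Hox genes higher, 1 lower and 9 not passing, over all genes or adjusted over the list alone (camera adjusted p = 7.02e-09; adjusted p = 0.252 with an estimated correlation). From 48 to 96 h Hmga2 rose from 12.7 to 61.9 TPM (log2 change 2.19, SE 0.07, adjusted p = 4.63e-06) and Nanog from 67.4 to 146, while Rex2 went from 105 to 27. Of 36 germline genes 3 rose, 23 fell and 10 did not pass, or 3 and 24 adjusted over the list alone (camera adjusted p = 5.55e-12), and that call held with an estimated correlation (adjusted p = 0.0269). Of 13 fibroblast markers 9 rose and 4 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 0.0386, but 0.0521 without the 48 h replicate 1; adjusted p = 0.322 with an estimated correlation), and 5 rose without the 48 h replicate 2. In all 2397 genes rose and 2718 fell from 24 to 48 h, 5115 in total, where median-of-ratios scaling gave 2607 and 2563, and 3856 rose and 1504 fell from 48 to 96 h, 5360 in total, where median-of-ratios scaling gave 2562 and 2388. The first count was 3022 and 3102 without the 24 h replicates 1 and 2, and 2923 and 3036 without the 48 h replicates 1 and 2. The second was 2957 and 2596 without the 48 h replicates 1 and 2.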

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

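The tests that weigh explanations for the patterns of fibroblast and interferon, germline and 2-cell stage genes, and the order of the epiLC genes in the QKO libraries, were chosen after the results were seen. 3 earlier tests were set aside because the pattern itself fixed their outcome, and the thresholds of their replacements were set after the values were known.

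The knockdowns differed from one another in the 2i medium. Stress and ATF4 genes were lower with shE2F6 than with shBcat (camera adjusted p = 0.000218, median log2 difference -0.81). Some of them had risen with shBcat against shGFP, while most had not passed there. Genes of the 2-cell stage were higher with shHP1r than with shBcat (2.46e-30, median 3.66) and than with shE2F6 (1.36e-14, median 2.65). Glycolysis genes were lower with shHP1r than with shE2F6 (0.000916, median -0.38), a call lost without shHP1r replicate 1 (0.0524). With an estimated correlation adjusted p was 0.535, 0.0401, 0.307 and 0.730 for these 4 differences. Both shE2F6 libraries carried the high mitochondrial share, and median-of-ratios scaling shifted all genes by 0.21 in the comparison with shBcat and by -0.22 in that with shHP1r. Across tables, and therefore with no test of the difference, the libraries with shBcat moved in opposite directions in QKO cells and in epiLC at 96 h for glycolysis genes (median log2 change higher in QKO by 0.985) and cholesterol genes (by 0.657). They also did so in V6.5 and QKO cells in 2i for the genes that rose in epiLC (higher in V6.5 by 0.918) and those that fell (a V6.5 minus QKO difference of -0.63). Of the genes that rose in epiLC, 93 of 147 tested in QKO cells ranked the shGFP libraries there in the order of the fibroblast median, and 6 are members of the fibroblast or interferon lists.

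The fall of fibroblast and interferon genes with shBcat in QKO cells may come from a varying share of admixed cells. Within the 3 shGFP libraries, 18 of 20 fibroblast list members and 16 of 21 interferon members ranked the libraries in the order of the fibroblast median, as 25.6% of 15521 other genes did and 16.7% of random orders would. Of the fibroblast members below 1 TPM in V6.5 cells in 2i the most abundant, Col3a1, Col1a1 and Acta2, stood at 170, 91.7 and 79.9 TPM in shGFP libraries, while V6.5 cells in 2i held 7 fibroblast and 10 interferon members at 1 TPM or more, and the labels name no sort that would remove such cells. A fall of 6 interferon members by a larger fold than any fibroblast member (7.74 at most) counts against a smaller admixed share as the whole cause for those 6, but they lay at 1.07 TPM or less with shBcat, so it stays open for the list, as does an effect of β-catenin on these genes, which was not tested apart. The real split of the 6 libraries called 334 genes and the highest other split 2, 1 of 10 splits reaching the real count, and 10 splits are too few for a share under 0.05.

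The rise of germline genes with shE2F6 coincided with the high mitochondrial share of both shE2F6 libraries and shGFP replicates 3 and 4. With that set of libraries as a term, 15 germline members rose and the list had a camera adjusted p of 3.69e-31, which argues against the set as the whole cause. A role of E2F6 in silencing these genes is a hypothesis that the design names, and it stays open beside other technical differences that the labels do not record.

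The 2-cell stage genes moved down with shBcat and up with shHP1r in V6.5 cells in 2i. Reads shared among the Zscan4 copies do not account for this, since members outside that family had a median difference of 3.32 with 11 called. Several of those belong to the Usp17l and Tcstv families, whose members may share reads as well, so the 11 need not be independent. The library set with a high mitochondrial share holds no shBcat or shHP1r library. By design it could not give their difference from each other, and its term bears only on each change over shGFP. With that term the medians were 1.79 with shHP1r and -1.89 with shBcat, so both directions stayed. Differences in the share of cells passing through a 2-cell-like state could underlie the pattern, but no data on single cells were used here, and effects of the hairpins beyond their targets stay open. The list moved up with shBcat in other cells. In QKO cells its median log2 change was 0.17 (camera adjusted p = 0.00013, and 0.578 with an estimated correlation), and 18 of 18 genes did not pass. At 96 h of epiLC the median was 0.21 (1.95e-07, and 0.0982 with an estimated correlation), with 2 genes up and 16 not passing.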

How the results depend on the processing

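The library set term, the averaging of libraries in pairs, the overlaps and the epiLC sets without fibroblast and interferon list members were added after the data were seen, and the other alternatives were fixed before. Of the named genes' values with single libraries left out, 765 kept direction and side of the threshold, 110 lost the call, 2 gained it and 13 changed direction, and under the other settings these numbers were 1019, 110, 6 and 2. For 68 of the gene list results given in the text they were 343, 17, 9 and 1 with libraries left out, and 267, 58, 5 and none under the other settings. Where a library left out leaves a group with 1 library, that library is assumed to vary like the other groups. Depth is unknown, so whether a low gene was undetected or absent cannot be judged, and changes of genes near 1 FPKM or TPM are the least certain. Unless stated, the cause was not tested.

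A 2-fold minimum, which by construction lowers counts, left 348 genes for shBcat, 28 for shE2F6 and 402 for shHP1r in V6.5 cells, 738 between shE2F6 and shBcat, 622 between shHP1r and shBcat, 898 between shHP1r and shE2F6, 79 in QKO cells, 2943, 3370 and 2675 for epiLC at 24 h, 48 h and between them, 44 at 96 h, and 498 and 324 for the later steps with shBcat. With a minimum of 5 in 2 libraries the counts were 829 (shBcat), 284 (shE2F6), 481 (shHP1r), 734 (shHP1r and shBcat), 887 (shHP1r and shE2F6) and 855 (QKO). With no filter they were 1847 (shHP1r), 3391 (shHP1r and shE2F6), 14 (QKO) and 341 (96 h). With the compared groups alone they were 36 (shE2F6), 557 (shHP1r), 8982 (shE2F6 and shBcat), 5291 (shHP1r and shE2F6) and 268 (96 h). A pseudocount of 0.1 gave 278 for shE2F6 and 570 in QKO cells, no variance trend gave 19 in QKO cells, and median-of-ratios scaling gave 240 for shE2F6.

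With the library set term the counts were 3473 (shBcat), 257 (shE2F6), 3296 (shHP1r), 1344 (shE2F6 and shBcat), 3817 (shHP1r and shBcat) and 844 (shHP1r and shE2F6), and the shared genes were 89, 626 and 84 for shBcat with shE2F6, shBcat with shHP1r and shE2F6 with shHP1r. All 1255 genes called for shBcat and all 1093 for shHP1r kept their call, as did 116 of 153 for shE2F6, all 1341 for shHP1r against shBcat, 714 of 2196 for shE2F6 against shBcat and 620 of 2230 for shHP1r against shE2F6, the last 2 losing 1482 and 1610. Controls split 3 and 3 gave medians of 4, 38 and 2.5 shared genes. For the epiLC sets with shE2F6, the library set term turned the falling set to a rise (adjusted p = 0.00716) and brought the fall of the rising set past the threshold (0.000605). Without fibroblast and interferon list members the falling set with shE2F6 turned, with no call (0.971), and the other 7 kept direction and side of the threshold. With an estimated correlation the adjusted p of the sets was 0.294 for both sets with shBcat in V6.5 cells, the rising set with shHP1r and the falling set in QKO cells, 0.709 for the falling set with shHP1r, and 0.462 for the rising set in QKO cells.

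With libraries averaged in pairs, which leaves 1 sample per knockdown and the spread of 3 shGFP pairs, limma called 0 genes for shBcat, shE2F6, shHP1r, shE2F6 against shBcat and shHP1r against shE2F6, with 702, 209, 754, 731 and 942 at an unadjusted p under 0.05, and 144 for shHP1r against shBcat. The log2 changes of the targets were -3.93 for Ctnnb1, -1.45 for E2f6 and -3.02 for Cbx3, none past the threshold. The replicate numbers were not taken to pair the libraries. In QKO cells the deviations of libraries with the same number had correlations of -0.012, -0.042 and 0.131, and 2 of 6 libraries correlated best with their own number. At 96 h the correlation was 0.283, a single value from 2 pairs that cannot show pairing, and the block gave 771 genes. With the replicate number as a block the counts were 138 (QKO), 7685 (shE2F6), 609 (shHP1r), 7826 (shE2F6 and shBcat), 3319 (shHP1r and shBcat) and 8039 (shHP1r and shE2F6).

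Leaving out each library in turn gave 212 to 1224 genes for shBcat, 19 to 4165 for shE2F6, 420 to 1555 for shHP1r, 172 to 476 between shE2F6 and shBcat, 583 to 1573 between shHP1r and shBcat, 511 to 1916 between shHP1r and shE2F6, 8 to 932 in QKO cells, 274 to 454 at 96 h, 2923 to 3102 from 24 to 48 h with shBcat and 2596 to 4666 from 48 to 96 h. The log2 change of Ctnnb1 in QKO cells ranged from -3.18 to -2.80. Values that changed sign, with no call in either direction, were these. Axin2 in QKO cells stood at 0.0030 with median-of-ratios scaling and ranged from -0.076 to 0.018 with libraries left out, the highest without shBcat replicate 1. The adjusted p of Wnt target genes in QKO cells ranged from 0.776 to 0.996, and the list's direction turned without shBcat replicate 1 (0.937). Pou5f1 with shBcat in V6.5 cells ranged from -0.17 to 0.11, and was above 0 without shBcat replicate 1 (0.013) and shGFP replicates 1, 2, 5 and 6 (0.042, 0.051, 0.11 and 0.10). Ctnnb1 stood at 0.0047 with shE2F6 under the library set term. With shHP1r it ranged from -0.096 to 0.080, and was above 0 without shGFP replicates 1, 2, 5 and 6 (0.011, 0.020, 0.035 and 0.037) and shHP1r replicate 1 (0.080). Otx2 at 96 h ranged from -0.17 to 0.090, and was above 0 without control replicate 2 (0.090) and shBcat replicate 1 (0.026).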

Other observations

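The overlaps in this part were not planned and were chosen after the results were seen. At 48 h of epiLC imprinted genes rose in unmodified cells, 21 of 23 with 2 lower, over all genes or adjusted over the list alone (median log2 change 1.52, camera adjusted p = 1.32e-05; adjusted p = 0.117 with an estimated correlation). Mest, an imprinted gene expressed in mesoderm, went from 20.2 to 568 TPM (n = 2 each). Genes of the 2-cell stage fell at the same time, 13 of 18 with 5 not passing, over all genes or adjusted over the list alone (camera adjusted p = 0.000165; adjusted p = 0.425 with an estimated correlation). The neuroectoderm list had 16 of 17 members higher and 1 lower, over all genes or adjusted over the list alone (camera adjusted p = 0.000231; adjusted p = 0.141 with an estimated correlation). In the same comparison 13 of 15 fibroblast markers rose (camera adjusted p = 0.00121; adjusted p = 0.141 with an estimated correlation), and of 15 interferon genes 10 rose, 4 fell and 1 did not pass, over all genes or adjusted over the list alone (camera adjusted p = 0.410).

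The changes with shBcat in 2i and at 96 h of epiLC were set beside each other, in tables normalized separately. Of 12288 genes tested in V6.5 cells in 2i and at 96 h, 39 rose in both where independent lists share 11.3 (Fisher's exact test, p = 1.21e-11). They include the stress genes Chac1, Ddit3 and Nupr1, the amino acid genes Psat1 and Mthfd2, and the imprinted genes H19 and Grb10. Another 21 fell in both where independent lists share 17.0 (Fisher's exact test, p = 0.31), and 33 moved in opposite directions. Of 13842 genes tested in QKO cells and at 96 h, 9 rose in both where independent lists share 1.95 (Fisher's exact test, p = 0.000142), and 16 fell in both where independent lists share 4.92 (Fisher's exact test, p = 3.58e-05), and 15 moved in opposite directions. The 9 were Zfp640, Zfp978 and otherwise predicted genes with symbols that begin with Gm. The 16 include the target Ctnnb1 and 4 members of the interferon list, which fell together with fibroblast markers in QKO cells. At 96 h, of 13 fibroblast markers 2 rose, 1 fell and 10 did not pass, or 2 and 2 adjusted over the list alone. Their list had a camera adjusted p of 0.763 there, so the interferon genes fell at 96 h without a fall of the fibroblast list. The genes named in this paragraph were chosen after their values were seen. The stress and ATF4 list went down with shBcat in QKO cells, with a median log2 change of -0.23. Its camera adjusted p was 0.0348 there, and 0.578 with an estimated correlation. Of its members 21 did not pass, and 7 fell adjusted over the list alone. Fisher's exact test takes genes as independent, which they are not, so its p-values may be too small where genes move together. Across genes the fold changes had r = 0.02 and 0.01.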
